A study of Drosophila melanogaster with 18 samples.

How the data were processed

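Hemocytes of adult female Drosophila melanogaster were isolated, per the labels, with beads against a mouse CD8 fusion protein displayed by Hml-delta GAL4 cells, from 6 groups of 3 libraries: wild type (landing site control) or A2bp1 RNAi, each uninjected, injected with PBS or injected with S. aureus. Libraries of polyadenylated RNA were sequenced as single-end reads of 50 bases. The authors deposited a table of whole-number read counts per gene, not normalised, with 1 column per library. They also deposited a table of log2 values. In a check on the values, the deposited log2 table followed log2 of the quantile-normalised counts plus 1: of 163044 values compared at mean counts above 10, 90.1% lay within 0.01 and the largest difference was 0.0936. The submitters' processing notes name Trimmomatic and limma, without versions and without saying which step used limma. The aligner, the counting program, the genome build, the annotation release and the treatment of strand and multiply aligned reads are not given in the sources used here.

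Gene symbols came from a reference gene table matched by FlyBase identifier. 17387 of 17684 identifiers had a symbol and 297 had none. The Release 6 RefSeq assembly was used only for names, older symbols and the order of neighbouring genes. Samples were assigned to groups from the column names and labels, and none was left out. Replicate pairs were checked by the correlation of log2 CPM and by a chi-square of their counts per degree of freedom, which was 16.9 to 93.7, above counting error. The lowest and highest correlations were 0.974 and 0.989. A count of 3 corresponds to 0.107 to 0.167 CPM over the libraries, which covers counting error only.

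Counts were fitted in edgeR 4.0.16 under R 4.3.3, with TMM factors (0.788 to 1.13), genes kept by filterByExpr over the 6 groups (minimum count 10, minimum total 15), robust quasi-likelihood dispersions and two-sided F tests. All 18 libraries entered 1 fit with 6 group means, and Benjamini-Hochberg adjustment ran over the 9454 genes kept, at a threshold of 0.05. The 13 contrasts were the 3 pairs of treatments in each genotype, the genotype difference in each treatment and as their mean, and the 3 interactions. CPM in the text are normalised by TMM. With 3 libraries against 3 an exact permutation test cannot go below a two-sided p of 0.1, so no such test was used for single genes.

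The contrasts, the tests, the alternatives except 3, the gene lists and the rule for named genes were fixed before the data were examined. The rule names A2bp1. For the wild-type treatment contrasts and the mean genotype difference it names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, at a mean of at least 5 CPM in the higher group and with the same direction in every replicate. For other contrasts it names the first 5 each way, without the replicate condition for the interactions. For each gene list it names up to 4 members with the smallest p. Genes named outside the rule are said to be chosen after their values were seen.

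The lists covered antimicrobial peptides, bomanins and other Toll-induced peptides, the Toll, Imd and JAK-STAT pathways, JNK and wound response, secreted signals and chitinase-like factors, phagocytic receptors, actin and engulfment, phagosome and lysosome, plasmatocyte, crystal cell and lamellocyte markers, melanization and clotting, and markers of fat body, ovary and eggshell, muscle, gut, neuron and eye, and male reproductive tract. They also covered heat shock, ER stress, oxidative stress, glycolysis, iron and metal handling, cell cycle, ecdysone, autophagy, RNA-binding regulators, extracellular matrix and adhesion, cytosolic ribosomal proteins, mitochondrial genome transcripts and nuclear-encoded oxidative phosphorylation. A list needed 5 tested members, which left 32 lists; the male reproductive tract list had 2 of 23 tested and was not used. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. Some genes stand in more than 1 list.

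The fit was tested on simulated data in which 200 genes had their counts changed by a set factor in 1 group. Each gene's counts were drawn independently of other genes, and genes at the lowest mean levels were not among those changed. For the mean genotype difference the counts were changed in all RNAi-labelled groups, so more libraries carried the change there. At 1.5-, 2- and 4-fold edgeR recovered 41.8%, 80.6% and 90.9% for wild-type PBS against uninjected, 31.3%, 73.1% and 98.5% for wild-type S. aureus against uninjected and 31.3%, 73.1% and 93.9% for wild-type S. aureus against PBS. In the RNAi-labelled libraries the same contrasts gave 43.3%, 74.6% and 93.9%, then 40.3%, 79.1% and 97%, then 32.8%, 83.6% and 95.5%. The mean genotype difference gave 82.1%, 94% and 98.5%, and the difference in uninjected, PBS and S. aureus flies 32.8%, 76.1% and 92.4%, then 38.8%, 74.6% and 97%, then 37.3%, 77.6% and 95.5%. The interactions gave 9%, 44.8% and 86.4% for PBS against uninjected, 9%, 47.8% and 93.9% for S. aureus against uninjected and 7.5%, 47.8% and 93.9% for S. aureus against PBS. Unchanged genes called in a contrast numbered at most 10 in edgeR and 8 in limma-voom, and 9 to 28 in DESeq2.

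Alternatives tried were RLE size factors, no count filter, DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, a replicate block by Set number, only the libraries compared, and leaving out each library in turn. The 3 alternatives chosen after seeing the data were leaving out mitochondrial transcripts, scaling by total counts alone, and limma-voom with library weights. Correlations across libraries used permutation tests. Splits of the libraries into other groups of the same sizes were refitted to see how many genes they called.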

Results

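Polyadenylated RNA was sequenced from blood cells (hemocytes) of adult female Drosophila melanogaster. The hemocytes displayed a mouse CD8-GFP fusion protein driven by Hml-delta GAL4, a driver active in most plasmatocytes, the phagocytic blood cells of the fly, and were pulled out with magnetic beads that bind mouse CD8. Flies carried either a hairpin against A2bp1 or, as the wild-type control, the landing site without a hairpin. The labels spell the hairpin line in 2 ways, HMS0048 in the genotype and HMS00478 in the library names. A2bp1, named Rbfox1 in current annotation, encodes an RNA-binding protein that regulates splicing. Flies of each genotype label were left uninjected, injected with PBS as a wounding control, or injected with Staphylococcus aureus, a Gram-positive bacterium, at an optical density of 5.0, and were kept for 3 h at 25 °C. Each of the 6 groups held 3 libraries, so that 18 libraries were compared, and the labels say that flies were injected in groups of 60. The labels number the libraries of each group by Set and do not say whether they came from separate cultures or days, so the p-values measure the spread between these libraries.

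Total counts per library ranged from 20478148 to 25569518, with a median of 22961164. The mitochondrial large ribosomal RNA, mt:lrRNA, took 28.5% to 38.5% of all counts, and transcripts of the mitochondrial genome together took 41.4% to 57.5%. Hml, the plasmatocyte gene behind the driver, ranged from 194 to 881 CPM (read counts scaled to a common library total) over the libraries. Abundant transcripts of other tissues were present in every library: the yolk protein gene Yp2 at 1100 to 3720 CPM, the eggshell gene Cp15 at 627 to 3390 CPM, the opsin gene ninaE at 529 to 1440 CPM, the germline gene osk at 54.1 to 123 CPM and the muscle gene Mhc at 58 to 121 CPM. Of the 17684 genes in the count table, 4597 were listed at 0 in all 18 libraries. These included RpS6, RpL41 and RpS10a, 3 of the 81 cytosolic ribosomal protein genes, while the 76 ribosomal protein genes that were tested had a median total of 448956.5 counts over the 18 libraries. The peptide genes Mtk, Def and edin and the transcription factor gene Rel were also listed at 0, and a listed 0 is not read here as absence of the transcript. Levels below are mean CPM ± SD with n = 3 libraries per group unless another n is given, fold changes are on the log2 scale with their standard errors (SE), and adjusted p-values come from edgeR's two-sided quasi-likelihood test over 9454 genes. The largest changes named are those among genes past the threshold that averaged at least 5 CPM in the higher group and whose replicates did not overlap between groups. For the mean genotype difference the same sign in all 3 treatments was needed in place of the last condition.

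The targeted gene was examined first, as a check of the genotype labels. A2bp1 (Rbfox1, FBgn0052062) stood at 20.2 ± 2.64 CPM in the 9 wild-type libraries and at 19.5 ± 2 CPM in the 9 libraries labelled A2bp1 RNAi (SD, n = 9 each), with 16.4 to 25.5 and 16.9 to 23.5 CPM in single libraries and 353 to 664 counts behind each value. The mean difference over the 3 treatments was −0.05 (SE 0.08, 95% confidence interval −0.23 to 0.13, adjusted p = 0.838), an interval that allows a fall of at most 14.6%. Within treatments the difference was −0.10 in uninjected flies (95% interval −0.40 to 0.21), −0.05 after PBS (−0.36 to 0.26) and 0.00 after S. aureus (−0.31 to 0.31). The transcript count of A2bp1 therefore did not separate the genotype labels, whose hairpin line is spelled in 2 ways, and the libraries are called RNAi-labelled in what follows.

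**Figure D1:**
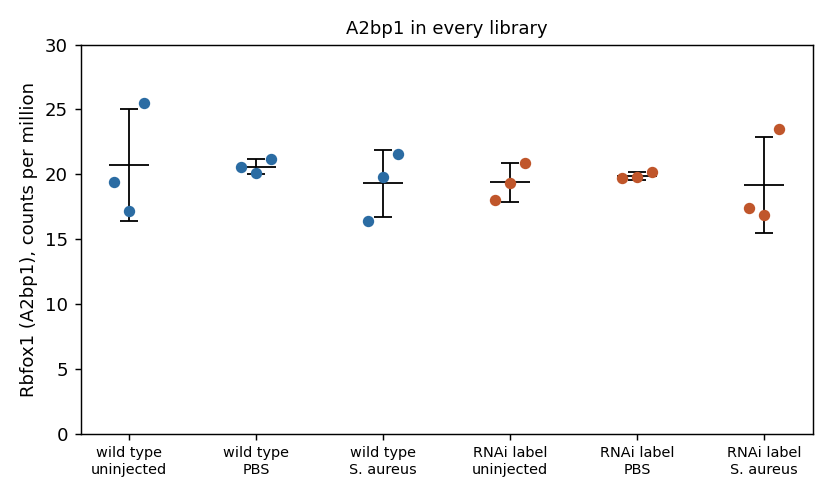
CPM of Rbfox1 (A2bp1) in each of the 18 libraries (points) by genotype label and treatment, with the group mean (long line) and SD (bars), n = 3 per group. All libraries lie between 16.4 and 25.5 CPM, and the ranges of the genotype labels overlap in every treatment.

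The first comparison asked how wild-type hemocyte preparations responded to sterile wounding. After PBS, the cecropin transcripts CecA2 and CecA1, which encode short bactericidal peptides, were higher than in uninjected flies. CecA2 rose from 3.61 ± 2.19 to 16.3 ± 3.7 CPM (log2 fold change 2.18, SE 0.43, adjusted p = 0.0321) and CecA1 by 1.79 (SE 0.39, adjusted p = 0.0473). ple, which encodes the tyrosine hydroxylase of dopamine and melanin synthesis, rose by 1.68 (SE 0.36), and the glutathione transferase gene GstD5 rose by 3.16 (SE 0.58) from a level of 0.515 ± 0.177 CPM. Transcripts of eggshell, yolk and digestive proteins were lower: the vitelline membrane gene Vm34Ca fell from 619 ± 60.9 to 105 ± 18.6 CPM (−2.56, SE 0.37, adjusted p = 0.0066), Yp3 from 1190 ± 346 to 349 ± 45.4 CPM (−1.77, SE 0.28) and the protease gene Jon25Biii from 64.8 ± 13.6 to 24.1 ± 6.76 CPM (−1.43, SE 0.26).

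In total 45 genes were higher and 35 lower after PBS at an adjusted p under 0.05. Besides the cecropins and ple, the higher genes with the largest changes were CG13324 (2.12), peg (2.05, SE 0.22, adjusted p = 0.000371), CG16978 (2.00), CG33110 (1.95), CG7778 (1.74), CG16898 (1.74) and CG12780 (1.64). The lower genes were led by CG34166 (−2.83), Vm34Ca, the sorbitol dehydrogenase gene Sodh1 (−2.44, SE 0.27), the protease genes Jon25Bii (−2.33) and Jon25Bi (−2.22), Vm26Aa (−2.15), Cyt-b5-r (−2.04), Yp3, Vm26Ac (−1.71) and CG6503 (−1.45). Adjacent or near-identical gene copies such as CecA1 and CecA2, AttA and AttB, Jon25Bi and Jon25Bii, Amy-p and Amy-d and the Hsp70 genes can share reads, and how the counting treated such reads and the strand is not given in the sources used here, so values of single copies and of antisense transcripts are uncertain.

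By gene list, 2 of 12 antimicrobial peptide genes rose and 0 fell (4 higher when adjusted over the list alone), with a median change of 0.65 and a camera adjusted p of 1.37e-06 (adjusted p = 0.459 with an estimated correlation). This list carried the mark of 1 library: in replicate 2 of the wild-type uninjected group AttA stood at 44.1 CPM, against 4.82 and 8.96 CPM in replicates 1 and 3, and without that library the median was 2.21 and 4 members rose. The median was 0.21 without replicate 1 and 0.33 without replicate 3 of the uninjected group, and 0.33 without replicate 2 of the PBS group. Of 21 JNK and wound response genes 1 rose (ple; 3 when adjusted over the list alone; camera adjusted p = 0.000318, adjusted p = 0.459 with an estimated correlation), and Ets21C, a JNK target, stood at 1.55 (adjusted p = 0.111). Of 31 oxidative stress and detoxification genes, GstD5, GstE6 (0.73) and GstE1 (0.83) rose and 0 fell, with 10 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.459 with an estimated correlation). In the fat body list 5 of 21 genes fell, among them Yp1 (−1.35), Yp3, Obp99a (−1.36) and fit (−2.55), and 7 when adjusted over the list alone (camera adjusted p = 1.09e-11, adjusted p = 0.0901 with an estimated correlation). In the ovary and eggshell list 3 of 24 fell, Vm34Ca, Vm26Aa and Vml (−1.02), and 12 when adjusted over the list alone (camera adjusted p = 6.15e-11, adjusted p = 0.102 with an estimated correlation). In the gut list 3 of 28 fell, the Jon25B genes, and 13 when adjusted over the list alone, with a median of −0.84 (camera adjusted p = 9.93e-15, adjusted p = 0.378 with an estimated correlation). The 18 muscle markers had a median of 0.10, with 0 past the threshold and 1 higher when adjusted over the list alone. The fat body median of −0.48 was −0.72, −0.17 and −1.01 without replicate 1, 2 or 3 of the uninjected group and −1.23 without replicate 1 of the PBS group. Without replicate 3 of the uninjected group the JNK median of 0.16 was 0.07 and the ovary and eggshell median of −0.37 was −0.23, and without replicate 3 of the PBS group the oxidative stress median of 0.18 was 0.10. Leaving out 1 library gave 9 to 77 genes, with 20, 35 and 9 genes without replicate 1, 2 or 3 of the PBS group and 29 without replicate 3 of the uninjected group. DESeq2 called 225 genes, edgeR on only the 6 libraries compared 34, and scaling by total counts alone changed the split of higher and lower genes to 14 and 34.

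The second comparison asked how wild-type preparations responded to S. aureus, the wound included. Immune peptide transcripts rose. CecA1 went from 7.12 ± 3.58 CPM in uninjected flies to 102 ± 4.82 CPM (log2 fold change 3.83, SE 0.41, adjusted p = 0.000277) and CecC from 7.41 ± 6.23 to 68.6 ± 9.71 CPM (3.21, SE 0.45). Bomanins, short secreted peptides induced through the Toll pathway, rose likewise: BomS1 from 25.5 ± 12.2 to 203 ± 64.4 CPM (2.99, SE 0.41), BomBc1 from 21.9 ± 14 to 196 ± 39.7 CPM (3.16, SE 0.47) and BomT1 from 4.49 ± 3.26 to 45.3 ± 9.36 CPM (3.33, SE 0.41). The lower transcripts included Cyt-b5-r (−3.30, SE 0.41), Sodh1 (−2.69, SE 0.27), Miox, which encodes the myo-inositol oxygenase (−2.34, SE 0.38), and apolpp, which encodes the major lipoprotein of the hemolymph (134 ± 45.4 to 39.1 ± 0.803 CPM, −1.78, SE 0.24).

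There were 153 higher and 40 lower genes. CecA2 (4.04), CG7778 (3.89, SE 0.26, adjusted p = 1.25e-06), CG33462 (3.54), CG16772 (3.52) and CecB (3.19) completed the 10 largest rises, and CG4950 (−2.19), Obp99a (−1.94, SE 0.15, adjusted p = 2.31e-06), CG6503 (−1.83), CG4716 (−1.67), CG1468 (−1.55) and CG16758 (−1.49) the 10 largest falls. Of 12 antimicrobial peptide genes 5 rose and of 19 bomanins and other Toll-induced peptide genes 12 rose, with 9 and 14 when adjusted over the list alone and medians of 2.52 and 2.07. Both lists passed camera (adjusted p = 3.38e-25 and 2.44e-34) and held with adjusted p = 0.034 with an estimated correlation. Without replicate 2 of the uninjected group, the library with raised peptide transcripts, the antimicrobial peptide median was 4.10 and 9 members rose, and PGRP-SB1 of the Imd list stood at 3.60 in place of 2.38. In the list of the Imd immune pathway 4 of 17 genes rose, PGRP-LA (1.31, SE 0.14), key (0.61), PGRP-SB1 (2.38) and pirk (1.40), with 10 when adjusted over the list alone (camera adjusted p = 1.22e-11, adjusted p = 0.034 with an estimated correlation). In the Toll list 5 of 18 rose, among them the inhibitor gene cact (0.76, SE 0.12), the protease gene Hayan (2.30), the receptor gene PGRP-SA (1.95) and the ligand gene spz (0.52), with 8 when adjusted over the list alone (camera adjusted p = 8.23e-07, adjusted p = 0.114 with an estimated correlation). The Imd median of 0.42 was 0.27 without replicate 3 of the uninjected group, and the Toll median of 0.30 was 0.19 without replicate 2 of the S. aureus group.

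Of 20 melanization and clotting genes 6 rose, including Hayan, Pu (0.56), Ddc (1.20) and Sp7 (0.66), and 7 when adjusted over the list alone (camera adjusted p = 1.11e-06, adjusted p = 0.0905 with an estimated correlation). In the JAK-STAT list 2 of 15 rose, Socs36E (0.64) and the cytokine gene upd3 (1.36), with 4 when adjusted over the list alone (camera adjusted p = 0.00903, adjusted p = 0.386 with an estimated correlation). In the JNK and wound list 3 of 21 rose, Ddc, Gadd45 (1.35) and cher (0.81), with 5 when adjusted over the list alone (camera adjusted p = 1.01e-06, adjusted p = 0.178 with an estimated correlation). Of 31 actin and engulfment genes Act5C rose (0.74, SE 0.13), 5 when adjusted over the list alone, and 29 of 31 values were positive (camera adjusted p = 8.23e-07, adjusted p = 0.386 with an estimated correlation). Of 23 phagocytic receptor genes Dscam1 rose (0.57, SE 0.13) and 0 fell, with 3 higher and 1 lower when adjusted over the list alone. The fat body list held 3 falls in 21 genes, fit (−5.35), Obp99a and apolpp, with 6 when adjusted over the list alone (camera adjusted p = 1.79e-09, adjusted p = 0.0441 with an estimated correlation). From 3.64 ± 0.96 CPM in uninjected flies, fit ended below the level of 3 counts, so the size of its fall is uncertain. The fat body median of −0.38 was −0.24 without replicate 2 of the uninjected group, the wild-type library highest for these markers, and −0.24 without replicate 3 of the S. aureus group, and the same number of members fell. Of 19 plasmatocyte markers 0 passed, with 1 lower when adjusted over the list alone, a median of −0.13 and Pxn at −1.06 (adjusted p = 0.0695). This median has no firm direction, since it turned to 0.22 without replicate 2 of the uninjected group and to 0.05 without replicate 3 of the S. aureus group, and was −0.29 and −0.32 without replicate 1 or 3 of the uninjected group and −0.35 without replicate 2 of the S. aureus group. Medians also moved for melanization genes, from 0.45 to 0.28 without replicate 1 of the uninjected group, for actin genes, from 0.18 to 0.11 without replicate 3 of that group, and for JAK-STAT genes, from 0.12 to 0.02 and 0.08 without replicate 1 or 2 of the S. aureus group and 0.07 without replicate 3 of the uninjected group. With 1 library left out there were 107 to 253 genes, with 122 and 109 without replicate 1 or 3 of the uninjected group and 107 without replicate 2 of the S. aureus group. DESeq2 called 318 genes and edgeR on only the 6 libraries compared 27.

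**Figure D2:**
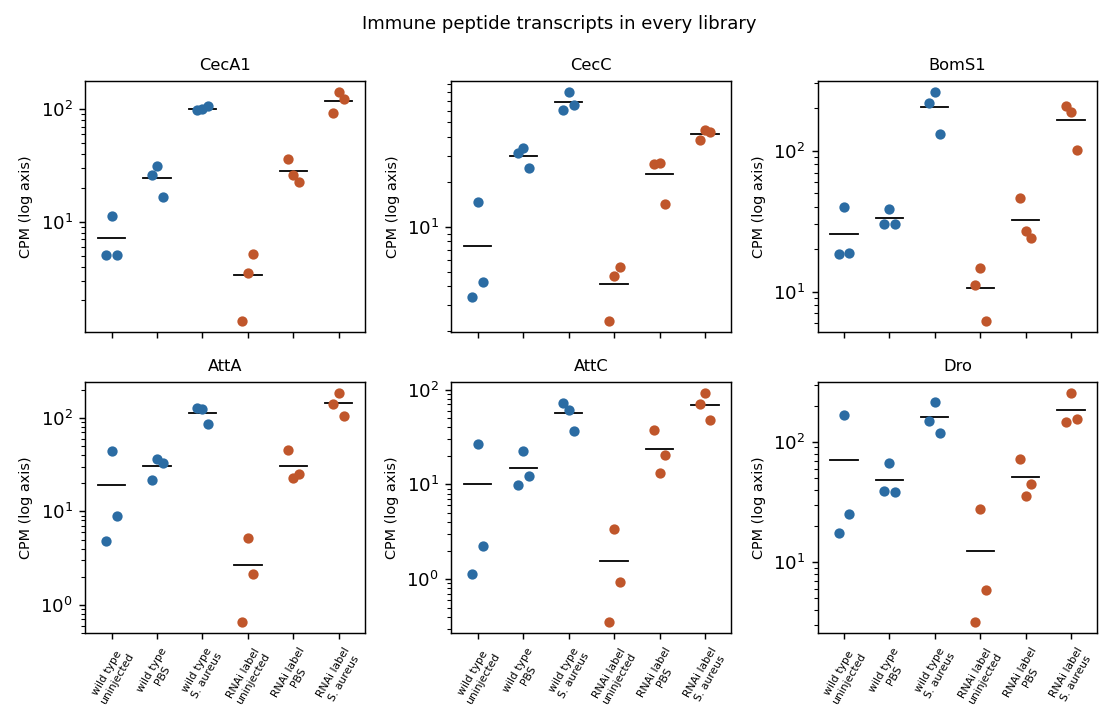
CPM (log axis) of 6 immune peptide transcripts in each of the 18 libraries, with the group mean as a line, by genotype label and treatment. CecA1 averaged 7.12 CPM in wild-type uninjected, 24.7 CPM in PBS and 102 CPM in S. aureus libraries, and 1 wild-type uninjected library lies above the other uninjected libraries for AttA at 44.1 CPM.

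The third comparison asked what bacteria added to the wound in wild-type flies. Bomanin transcripts were again higher, BomS1 at 203 ± 64.4 against 33 ± 4.84 CPM after PBS (log2 fold change 2.62, SE 0.41, adjusted p = 0.0114), BomBc1 by 2.37 (SE 0.45), BomT1 by 2.26 (SE 0.38) and BomS3 by 2.08 (SE 0.39). Cecropins rose beyond the PBS level, CecB by 2.54 (SE 0.53), CecA1 by 2.04 (SE 0.38) and CecA2 by 1.86 (SE 0.40). Eggshell and gut transcripts were higher than after PBS, Vm34Ca by 1.67 (SE 0.36), Vml by 0.90 (SE 0.19), Jon25Bi by 1.76 (SE 0.38) and the amylase gene Amy-d by 1.43 (SE 0.30). Miox fell by 2.03 on the log2 scale (SE 0.38).

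There were 63 higher and 15 lower genes. CG4757 (3.46), CG33462 (3.38), CG16772 (2.67), a gene with no symbol in the name table (FBgn0033835, 2.25) and CG7778 (2.15, SE 0.24, adjusted p = 0.0015) were also among the 10 largest rises. The lower genes were led by CG16898 (−2.19), the neprilysin-like gene Nepl4 (−2.09), Miox, CG33110 (−1.44), CG31205 (−1.21), Gasp (−0.94), nord (−0.90), se (−0.75), uzip (−0.60) and Akr1B (−0.55). Of 12 antimicrobial peptide genes 3 rose, and 6 when adjusted over the list alone (camera adjusted p = 1.26e-08, adjusted p = 0.349 with an estimated correlation). Of 19 bomanins and other Toll-induced peptide genes 5 rose, and 15 when adjusted over the list alone (camera adjusted p = 6.54e-21, adjusted p = 0.31 with an estimated correlation). Toll members cact (0.87), spz (0.57) and SPE (1.17), which encodes the protease that activates spz, rose among 18, and Imd members PGRP-LA (0.86) and PGRP-SC2 (1.53) among 17, with 6 and 3 when adjusted over the list alone (camera adjusted p = 2.13e-06 and 2.22e-05, adjusted p = 0.324 with an estimated correlation for both). Of 28 gut markers 2 rose, and 8 when adjusted over the list alone, with a median of 0.82 (camera adjusted p = 4.7e-14, adjusted p = 0.324 with an estimated correlation). Of 24 ovary and eggshell markers 2 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.000279, adjusted p = 0.411 with an estimated correlation), and their median of 0.35 was 0.15 without replicate 1 of the S. aureus group. This comparison and the first share the PBS libraries, so opposite changes in them are not independent. Fits without 1 library gave 5 to 73 genes, with 22 and 23 without replicate 1 or 2 of the S. aureus group and 5, 28 and 16 without replicate 1, 2 or 3 of the PBS group. DESeq2 called 237 genes, and scaling by total counts alone moved the median of all genes by 0.15 and gave 105 higher and 8 lower genes.

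**Figure D3:**
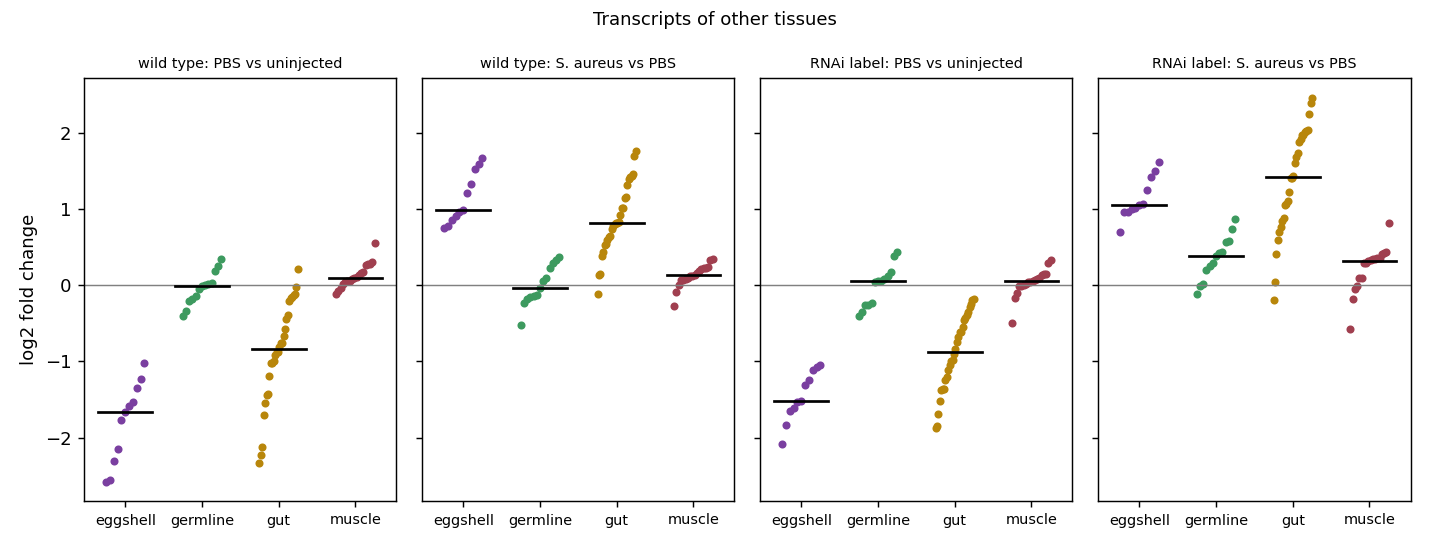
Log2 fold changes (y axis) of the tested eggshell, germline, gut and muscle marker genes (points) in 4 comparisons, with the median of each list as a line. In wild-type flies after PBS the 11 eggshell genes lay between −2.58 and −1.02 and the 13 germline genes between −0.40 and 0.34.

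In the RNAi-labelled libraries, PBS was followed by changes in cecropins and in yolk, eggshell and digestive transcripts. CecA2 rose from 2.13 ± 1.56 to 19.3 ± 3.33 CPM (log2 fold change 3.17, SE 0.46, adjusted p = 0.00878), CecA1 by 3.07 (SE 0.42), CecC by 2.44 (SE 0.46) and BomT1 by 3.01 (SE 0.51). Vm34Ca fell from 669 ± 78.3 to 157 ± 9.51 CPM (−2.09, SE 0.36), Yp3 from 1190 ± 137 to 423 ± 47 CPM (−1.49, SE 0.28), Sodh1 from 14.4 ± 2.7 to 2.3 ± 0.538 CPM (−2.63, SE 0.27) and apolpp from 151 ± 22.6 to 58 ± 5.95 CPM (−1.38, SE 0.24).

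There were 33 higher and 33 lower genes, and scaling by total counts alone gave 15 and 72 and moved the median of all genes by −0.16. lncRNA:CR32368 (3.17) was also among the 5 largest rises and CG34166 (−2.37), Cyt-b5-r (−2.07) and Jon25Bii (−1.88) among the 5 largest falls. Of 12 antimicrobial peptide genes 3 rose, all 12 when adjusted over the list alone, with a median of 3.04 (camera adjusted p = 5.17e-27, adjusted p = 0.0358 with an estimated correlation). Of 19 bomanins and other Toll-induced peptide genes 1 rose, and 11 when adjusted over the list alone (camera adjusted p = 7.98e-12, adjusted p = 0.233 with an estimated correlation). In the fat body list 5 of 21 fell, and 15 when adjusted over the list alone (camera adjusted p = 1.95e-15, adjusted p = 0.0282 with an estimated correlation). In the ovary and eggshell list 3 of 24 fell, and 10 when adjusted over the list alone (camera adjusted p = 1.82e-08, adjusted p = 0.127 with an estimated correlation), and in the gut list 2 of 28, and 6 when adjusted over the list alone (camera adjusted p = 2.18e-16, adjusted p = 0.187 with an estimated correlation). All 17 heat shock and chaperone genes had positive values, none past the threshold and 1 when adjusted over the list alone (camera adjusted p = 5.72e-06, adjusted p = 0.127 with an estimated correlation). Replicate 3 of the PBS group lay highest for this list, and without it the median went from 0.36 to 0.26 and 15 of 17 values were positive. The divalent metal transporter gene Mvl rose by 1.04 (SE 0.23). Of the genes higher after PBS, 16 passed in both genotype labels, against 0.157 from independent lists of the same sizes, and of those lower 21, against 0.122. These comparisons share no libraries, though they share 1 fit and its estimate of each gene's spread. Here and below, the figure for independent lists takes every gene as equally likely to pass, which may set it too low. Leaving out 1 library gave 6 to 47 genes, with 9 and 6 without replicate 1 or 2 of the uninjected group and 31, 11 and 11 without replicate 1, 2 or 3 of the PBS group. DESeq2 called 220 genes, limma-voom 31 and edgeR without a count filter 37.

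After S. aureus, the RNAi-labelled libraries had attacin transcripts far above the uninjected level. AttA, which encodes a glycine-rich antibacterial peptide, rose from 2.67 ± 2.34 to 143 ± 39.2 CPM (log2 fold change 5.72, SE 0.83, adjusted p = 0.00202), AttC from 1.55 ± 1.59 to 69.7 ± 22.1 CPM (5.45, SE 1.07) and CecA1 from 3.34 ± 1.95 to 119 ± 24.2 CPM (5.15, SE 0.44, adjusted p = 5.91e-05). BomT1 rose by 5.14 (SE 0.50) and BomS1 by 3.95 (SE 0.44). Cyt-b5-r fell by 3.21 on the log2 scale (SE 0.40) and apolpp by 1.57 (SE 0.24).

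There were 130 higher and 201 lower genes, against 108 and 67 when scaled by total counts alone. AttB (5.18) was also among the 5 largest rises, and CG31272 (−3.18), CG33301 (−2.64), CG32024 (−2.62) and CG3270 (−2.60) among the 5 largest falls. CG32024 and CG3270 were carried by replicate 1 of the uninjected group, without which they stood at −1.66 and −1.52 and did not pass. Of 12 antimicrobial peptide genes 10 rose and of 19 bomanins and other Toll-induced peptide genes 12 rose, with 12 and 15 when adjusted over the list alone (camera adjusted p = 2.01e-33 and 4e-35, adjusted p = 0.0279 with an estimated correlation for both). In the Toll list Hayan (2.59), SPE (1.45), PGRP-SA (2.38) and cact (0.60) rose and 1 of 18 fell, with 5 and 1 when adjusted over the list alone, and in the Imd list PGRP-LA (1.06), PGRP-SB1 (4.22) and PGRP-SC2 (1.48) rose among 17, with 3 when adjusted over the list alone (camera adjusted p = 0.00035 and 0.00139, adjusted p = 0.467 and adjusted p = 0.481 with an estimated correlation). Of 30 phagosome and lysosome genes 4 fell and 0 rose, with 11 when adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.662 with an estimated correlation). The 4 genes, Vha68-2 (−0.63), Vha100-2 (−0.71), VhaSFD (−0.59) and ATP6AP2 (−0.54), encode subunits or partners of a proton pump. With transcripts of other tissues in every library, their falls are not assigned to hemocytes or to lysosomes. The list median of −0.15 was −0.25 and −0.10 without replicate 1 or 3 of the S. aureus group and −0.23 without replicate 3 of the uninjected group. The Toll median of 0.15 was 0.25 without replicate 2 of the uninjected group, and the Imd median of 0.10 was 0.15 without replicate 1. Of 17 glycolysis genes Pgi (−0.35) and Ald1 (−0.45) fell, and 6 when adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.481 with an estimated correlation). Transferrin Tsf1 (1.53) and Mvl (0.86) rose and metallothionein MtnA (−0.73) fell. Genes past the threshold in both genotype labels numbered 77 higher and 26 lower, against 2.1 and 0.85 from independent lists of the same sizes. With 1 library left out there were 95 to 454 genes, with 95 and 208 without replicate 1 or 2 of the uninjected group and 124 and 179 without replicate 2 or 3 of the S. aureus group. DESeq2 called 616 genes and edgeR on only the 6 libraries compared 151.

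Against PBS, S. aureus gave the largest number of calls of any comparison, in the RNAi-labelled libraries. BomBc1 rose by 2.54 (SE 0.46), BomS1 by 2.35 (SE 0.40), CecA1 by 2.07 (SE 0.37) and the protease gene SPE by 1.28 (SE 0.26). Digestive transcripts rose, Jon25Bii from 1.58 ± 0.307 to 8.75 ± 4.98 CPM (2.46, SE 0.36) and Jon65Aiv from 120 ± 10.2 to 400 ± 221 CPM (1.74, SE 0.31). Without replicate 2 of the S. aureus group, the library highest for gut transcripts, these rises were 1.89 for Jon25Bii and 1.19 for Jon65Aiv. Cell cycle transcripts rose by smaller amounts, among them CycB, which is also on the ovary list, from 119 ± 10.8 to 198 ± 19 CPM (0.74, SE 0.13). The 13 germline and nurse cell genes moved with them, with a median of 0.38, equal to that of the cell cycle list, so these values do not tell dividing hemocytes from germline RNA in the preparation. The proton pump gene Vha100-2 fell from 843 ± 61.3 to 431 ± 68.7 CPM (−0.97, SE 0.17). Transcripts of other tissues were present in every library, so this fall is not assigned to hemocytes or to lysosomes.

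There were 575 higher and 442 lower genes. Scaling by total counts alone moved the median of all genes by 0.25 and gave 1830 higher and 136 lower genes, so directions here are relative to that median. CG10477 (3.36), CG4757 (3.28) and hiro (2.98) led the rises and CG42705 (−2.93), CG31272 (−2.90), CG42704 (−2.63), CG16898 (−2.17) and fusl (−2.03) the falls. CG10477 and hiro were carried by replicate 2 of the S. aureus group, without which they stood at 0.88 and 1.12 and did not pass. Of 28 gut markers 17 rose, and 21 when adjusted over the list alone, with a median of 1.42 (camera adjusted p = 8.56e-19, adjusted p = 0.41 with an estimated correlation). Replicate 2 of the S. aureus group lay highest for these transcripts, and without it 7 of them passed and the median was 0.99. Without replicate 2 or 3 of the PBS group 7 and 11 passed. Of 31 cell cycle genes 12 rose, among them cid (1.12), Cdk2 (0.77) and CycA (0.55), and 13 when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 2.36e-08, adjusted p = 0.605 with an estimated correlation). Of them 1 passed without replicate 2 of the S. aureus group, 1 without replicate 2 and 3 without replicate 3 of the PBS group, and 7 without replicate 3 of the S. aureus group. Of 24 ovary and eggshell markers 6 rose, and 11 when adjusted over the list alone (camera adjusted p = 3.73e-07, adjusted p = 0.41 with an estimated correlation), with 2 without replicate 2 of the S. aureus group and 1 and 3 without replicate 2 or 3 of the PBS group. Of 19 bomanins and other Toll-induced peptide genes 11 rose, with 14 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1e-11, adjusted p = 0.452 with an estimated correlation). The antimicrobial peptide list held 3 rises among 12, and 5 when adjusted over the list alone (camera adjusted p = 4.24e-05, adjusted p = 0.605 with an estimated correlation). Of 30 phagosome and lysosome genes 8 fell and 1 rose, with the same numbers when adjusted over the list alone, though the list median of −0.09 turned positive under scaling by total counts and was −0.19 without replicate 1 of the S. aureus group and −0.14 without replicate 1 of the PBS group (camera adjusted p = 0.00709, adjusted p = 0.72 with an estimated correlation). Glycolysis genes Pgi (−0.39), PyK (−0.35), Ald1 (−0.41) and Pfk (−0.41) fell among 17, and 5 when adjusted over the list alone, and this median of −0.12 too turned under that scaling and was −0.21 without replicate 1 of the S. aureus group (camera adjusted p = 0.0128, adjusted p = 0.684 with an estimated correlation). Of 17 heat shock and chaperone genes 2 fell, and 4 when adjusted over the list alone (camera adjusted p = 0.00386, adjusted p = 0.499 with an estimated correlation). Of these 1 fell without replicate 3 of the PBS group, the library highest for the list, where the median went from −0.35 to −0.28. None fell without replicate 2 of the PBS or of the S. aureus group, 3 without replicate 3 of the S. aureus group and 4 without replicate 1 of the PBS group. Of the genes in this comparison 45 higher and 7 lower also passed in wild type, against 3.83 and 0.701 from independent lists. Replicate 3 of the PBS group had 57.5% mitochondrial counts and a TMM factor of 0.788, the highest share and the lowest factor of the 18 libraries, and 338 genes were called without it. Fits without 1 library gave 155 to 1153 genes, with 155 without replicate 2 of the PBS group and 163 and 641 without replicate 2 or 3 of the S. aureus group.

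The next comparison asked what differed between the genotype labels over all treatments. 2 genes stood furthest apart: Peritrophin-A (FBgn0022770), a chitin-binding protein gene, averaged 6.13 ± 1.2 CPM in RNAi-labelled and 0.815 ± 0.464 CPM in wild-type libraries (SD, n = 9 each; log2 fold change 2.89, SE 0.27, adjusted p = 1.69e-05), and Dscam4, a gene of the immunoglobulin superfamily, averaged 19.1 ± 1.77 and 3.34 ± 1.18 CPM (2.52, SE 0.18, adjusted p = 1.52e-06). The acyl-CoA binding protein gene Acbp2 was higher by 1.13 (SE 0.09) and the pentose phosphate gene Zw by 0.48 (SE 0.08). Several genes of Toll and Imd signalling were lower, the neighbouring protease genes Hayan (−0.99, SE 0.22) and psh (−0.76, SE 0.16) and the peptidoglycan recognition genes PGRP-LF (−1.09, SE 0.26) and PGRP-LE (−0.58, SE 0.10), together with BomT1 (−1.28, SE 0.25). The BomT1 difference was −2.54 in uninjected flies (0.769 ± 0.14 against 4.49 ± 3.26 CPM, n = 3 each) and −0.59 after PBS. After S. aureus BomT1 averaged 27.4 against 45.3 CPM. In wild-type uninjected libraries Hayan (2.66 ± 1.75 CPM) and PGRP-LF (3.84 ± 2.56 CPM) also spread widely (n = 3).

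In total 122 genes were higher and 124 lower in the RNAi-labelled libraries. CG18258 (1.70), CG14456 (1.64), asRNA:CR44035 (1.19), CR12628 (1.06, SE 0.07, adjusted p = 8.27e-07), sordd2 (1.02), CG9459 (0.99) and CG17562 (0.99) were also among the 10 largest positive differences. lncRNA:CR32368 (−1.49), CG4927 (−1.36), CG41520 (−1.23), CG2930 (−1.20), the zinc transporter gene ZnT77C (−1.15, SE 0.14), jtb (−1.14), CG12522 (−1.06) and Srg3 (−1.05) were among the 10 largest negative ones. Of 18 Toll genes 2 were lower, Hayan and psh, and 0 higher, with 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00638, adjusted p = 0.494 with an estimated correlation). Of 17 Imd genes 2 were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.494 with an estimated correlation). All 12 antimicrobial peptide genes had negative values with a median of −0.70, none past the threshold over all genes or over the list alone (camera adjusted p = 0.00284, adjusted p = 0.592 with an estimated correlation), and without replicate 2 of the wild-type uninjected group the median went to −0.11 and, in uninjected flies alone, from −2 to −0.40. Plasmatocyte markers had a median of −0.39 with 18 of 19 values negative, none past the threshold and 7 lower when adjusted over the list alone (camera adjusted p = 6.03e-06, adjusted p = 0.494 with an estimated correlation), and this shift lay beside those of the immune lists. Phagocytic receptors had a median of −0.30, with 0 of 23 past the threshold and 6 lower when adjusted over the list alone (camera adjusted p = 6.03e-06, adjusted p = 0.494 with an estimated correlation). This list shares NimC1, eater, He, crq and Sr-CI with the plasmatocyte markers, so the 2 shifts are not independent. Of 31 actin and engulfment genes Act5C was lower (−0.32, SE 0.08), and 9 when adjusted over the list alone (camera adjusted p = 8.73e-07, adjusted p = 0.494 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes lay slightly higher, with a median of 0.11 and 60 of 62 values positive, none past the threshold over all genes or over the list alone (camera adjusted p = 4.56e-08, adjusted p = 0.592 with an estimated correlation), and the median was 0.07 without replicate 2 of the RNAi-labelled S. aureus group. The fits that left out 1 library gave 171 to 417 genes, with 417 without replicate 3 of the wild-type uninjected group, and DESeq2 called 422.

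**Figure D4:**
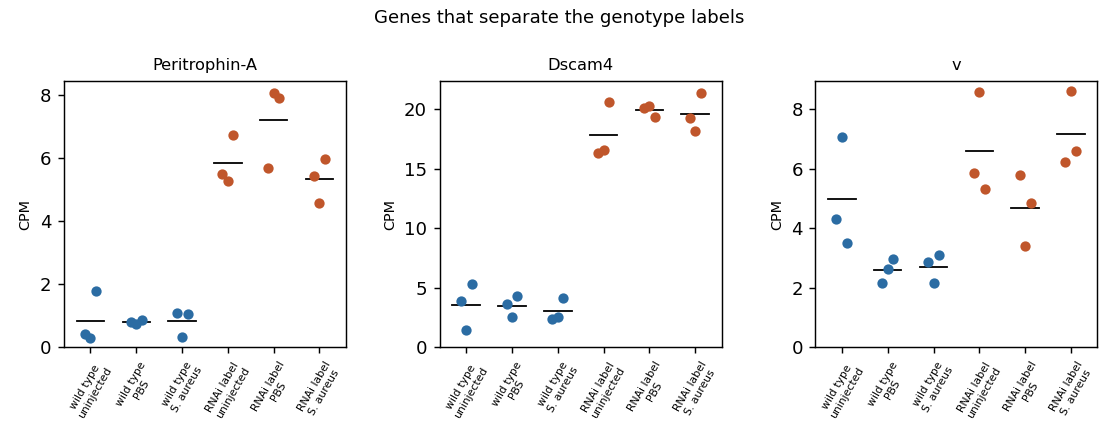
CPM of 3 genes in each of the 18 libraries (points), with group means as lines, by genotype label and treatment. Peritrophin-A averaged 6.13 CPM in the 9 RNAi-labelled and 0.815 CPM in the 9 wild-type libraries, Dscam4 19.1 and 3.34 CPM, and v differed with overlapping ranges.

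Within single treatments, with 3 libraries against 3, fewer genes passed between the genotype labels. In the self-test 32.8%, 38.8% and 37.3% of 1.5-fold changes were recovered in uninjected, PBS and S. aureus flies, against 82.1% for the mean difference. The smaller numbers therefore do not show that fewer genes differed within a treatment. In uninjected flies 21 were higher and 7 lower, led by Peritrophin-A (2.80, SE 0.46), Dscam4 (2.33, SE 0.31), hpRNA:CR32205 (1.26), CR12628 (1.16), CG17562 (1.03) and, lower, CG12522 (−1.20), the RNA-binding protein gene cpo (−0.72, SE 0.10), the circadian transcription factor gene cyc (−0.63, SE 0.11) and CG6454 (−0.48). After PBS 28 were higher and 7 lower, led by Peritrophin-A (3.15), Dscam4 (2.52), CG18258 (2.46), lncRNA:CR44922 (1.51), asRNA:CR44035 (1.37) and, lower, cpo (−0.70), Svip (−0.63), cyc (−0.54) and CG6454 (−0.46). After S. aureus 18 were higher and 24 lower, led by Dscam4 (2.72), Peritrophin-A (2.71), hpRNA:CR32205 (1.57), the tryptophan oxygenase gene v (1.40, SE 0.27), Acbp2 (1.16) and, lower, ZnT77C (−1.46), CG32444 (−1.24), CG12522 (−1.14), cpo (−1.10, SE 0.10, adjusted p = 0.000102) and PGRP-LE (−0.96, SE 0.18). After S. aureus all 76 cytosolic ribosomal protein genes had positive values with a median of 0.11, none past the threshold over all genes or over the list alone (camera adjusted p = 3.69e-05, adjusted p = 0.684 with an estimated correlation), and the median was 0.03 without RNAi-labelled S. aureus replicate 2 and 0.18 without replicate 1. Phagocytic receptors had a median of −0.65 in the same comparison, with 0 of 23 past the threshold and 3 lower when adjusted over the list alone (camera adjusted p = 3.65e-06, adjusted p = 0.488 with an estimated correlation). Plasmatocyte markers lay lower beside them, with a median of −0.41, 17 of 19 values negative and none past the threshold over all genes or over the list alone (camera adjusted p = 0.000489, adjusted p = 0.551 with an estimated correlation). Both lists hold NimC1, eater, He, crq and Sr-CI, so their medians are not independent. Without wild-type S. aureus replicate 2 the medians were −0.42 for the receptors and −0.20 for the markers. Fitting only the 6 libraries compared gave 0, 14 and 13 genes in edgeR, the 0 beside 550 genes at an unadjusted p under 0.05, while DESeq2 gave 115, 74 and 196. Without 1 of the libraries there were 4 to 51, 8 to 45 and 14 to 46 genes: in uninjected flies 8, 4 and 51 without RNAi-labelled replicate 1, 2 or 3 and 18 and 13 without wild-type replicate 2 or 3; after PBS 8 and 10 without wild-type replicate 1 or 2 and 13 and 12 without RNAi-labelled replicate 2 or 3; after S. aureus 15 and 14 without RNAi-labelled replicate 1 or 2 and 17 without wild-type replicate 2.

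The last comparisons asked whether the response itself differed between the genotype labels, as an interaction of genotype and treatment. For CecA1 the rise after PBS was 1.79 in wild-type and 3.07 in RNAi-labelled libraries, a difference that did not pass. CecA1 lay outside the naming rule for this contrast and was chosen after its values were seen. Over the 12 antimicrobial peptide genes the median difference for PBS against uninjected was 2, and 0.58 without wild-type uninjected replicate 2. For AttA the log2 difference of the S. aureus response from the uninjected level was 3.17 (SE 1, adjusted p = 0.48), with 44.1 CPM in wild-type uninjected replicate 2. No gene passed in edgeR's quasi-likelihood test for PBS against uninjected, S. aureus against uninjected or S. aureus against PBS, where 168, 924 and 531 genes had an unadjusted p under 0.05 against 473 expected by chance. limma-voom called 0 genes in all 3, and DESeq2 called 0, 1 and 1: CG32280 for S. aureus against uninjected (−0.80, adjusted p = 0.0305) and sog, which encodes a secreted BMP antagonist, for S. aureus against PBS (−0.94, adjusted p = 0.0169), both named after their values were seen. With 1 library left out, 1 gene passed in edgeR in each of 3 fits: CG11594 (−1.52) for S. aureus against uninjected without RNAi-labelled uninjected replicate 3, CG5065 (1.04) for the same comparison without RNAi-labelled S. aureus replicate 3, and sog (−1.09) for S. aureus against PBS without wild-type S. aureus replicate 1. The differences in the numbers of calls between the genotype labels are thus not differences in response that passed a test.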

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

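The lists below stood out because the response of their members to treatment differed between the genotype labels by camera at the preset correlation; the interaction contrasts were planned, and the tests that weigh explanations and the other splits of the libraries were chosen after the results were seen. None of the 32 lists passed with an estimated correlation, where the lowest adjusted p was 0.505 for PBS against uninjected, 0.713 for S. aureus against uninjected and 0.693 for S. aureus against PBS, or with fry (0.99, 0.43 and 0.542), and no gene passed in edgeR in any of the 3, beside 168, 924 and 531 at an unadjusted p under 0.05 and 0, 1 and 1 in DESeq2. Values are median log2 differences, RNAi-labelled response minus wild-type response. For PBS against uninjected they were 2 for antimicrobial peptides, 0.54 for bomanins and other Toll-induced peptides, 0.13 for cell cycle genes and 0.14 for mitochondrial genome transcripts. The median of each of these 4 lists moved by more than 1.5 times without some library: bomanins to 0.18 without wild-type uninjected replicate 2, cell cycle genes to −0.04 without wild-type uninjected replicate 3 and mitochondrial transcripts to −0.02 without RNAi-labelled PBS replicate 3.

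For S. aureus against uninjected the positive differences were 2.02 for antimicrobial peptides, 0.47 for bomanins, 0.42 for ovary and eggshell markers, 0.48 for gut markers, 0.59 for cell cycle genes, 0.11 for cytosolic ribosomal protein genes and 0.27 for mitochondrial genome transcripts. The negative ones were −0.20 for the Imd pathway, −0.28 for JNK and wound response, −0.21 for secreted signals, −0.22 for phagocytic receptors, −0.12 for actin and engulfment genes, −0.25 for phagosome and lysosome genes, −0.26 for neuron and eye markers, −0.18 for glycolysis, −0.15 for the ecdysone pathway and −0.14 for extracellular matrix and adhesion. Of these 17 medians 16 moved by more than 1.5 times without some library. Gut markers went to 0.10 and ribosomal protein genes to 0.02 without RNAi-labelled S. aureus replicate 2, and ovary markers to 0.27 without replicate 1 of that group. Without wild-type uninjected replicate 3 gut markers went to 0.29, cell cycle genes to 0.37, JNK genes to −0.12, secreted signals to −0.05, and phagosome genes to −0.10. Phagocytic receptors turned to 0.02 and mitochondrial transcripts went to 0.01 without wild-type S. aureus replicate 2, and neuron markers to −0.02 without wild-type uninjected replicate 2. For S. aureus against PBS the positive differences were 0.23 for ovary and eggshell markers, 0.50 for gut markers, 0.40 for cell cycle genes and 0.09 for ribosomal protein genes. The negative ones were −0.18 for the Imd pathway, −0.18 for JNK and wound response, −0.32 for secreted signals, −0.31 for phagocytic receptors, −0.13 for actin and engulfment genes, −0.22 for phagosome and lysosome genes, −0.25 for neuron and eye markers, −0.37 for heat shock genes, −0.14 for the ecdysone pathway and −0.15 for extracellular matrix and adhesion. Of these 14 medians 11 moved by more than 1.5 times without some library and none turned, while cell cycle genes, secreted signals and neuron markers did not move so far. Without RNAi-labelled S. aureus replicate 2 gut markers went to 0.04 and ribosomal protein genes to 0.00, without replicate 1 of that group ovary markers to 0.03, without wild-type S. aureus replicate 2 phagocytic receptors to −0.17, and without RNAi-labelled PBS replicate 3 heat shock genes to −0.18.

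The antimicrobial peptide difference may rest on 1 library, wild-type uninjected replicate 2, where AttA stood at 44.1 CPM against 4.82 and 8.96 CPM in the other replicates of its group. Without that library the median difference for S. aureus against uninjected went from 2.02 to 0.37, and for PBS against uninjected from 2 to 0.58. RNA carried over from fat body into the uninjected libraries stays open: the peptide mean and the fat body marker mean had r = −0.23 (exact permutation p = 0.697, adjusted 0.697) and rho = −0.43 (exact permutation p = 0.419, adjusted 0.419) over 6 libraries, in a family of 3 relations, and r was 0.49 without the 2 libraries farthest from the median, too few libraries to decide. A difference in the flies of that library, such as an infection before the experiment, was not tested.

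The real grouping gave 0 interaction genes in each contrast, a count that every split reaches, so that 100 of 100 drawn splits of the libraries within treatments gave as many for PBS against uninjected, 100 of 100 for S. aureus against uninjected and 100 of 100 for S. aureus against PBS, and these counts say nothing about the lists above. The highest other splits gave 2, 741 and 5 genes, and what the split with 741 separates was not examined.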

How the results depend on the processing

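All alternatives were planned before the data were examined except 3, chosen after seeing them: without mitochondrial transcripts, total counts only, and limma-voom with library weights. Of 310 calls of named genes none reversed under any alternative. Calls lost their adjusted p under 0.05 in 1 case with DESeq2, 9 with RLE size factors, 10 with a replicate block, 12 of 309 without mitochondrial transcripts, 19 with the deposited log2 values, 35 with library weights, 40 with limma-voom, 53 without a count filter, 89 with total counts only and 127 of 276 when only the contrasted groups were fitted, where fewer libraries estimated the spread. With 1 library left out 847 of 2268 calls were lost. RLE size factors, the deposited log2 values and leaving out mitochondrial transcripts kept every count of genes within 1.5 times. The named genes were picked for passing the threshold, and those with the largest treatment changes for replicates that did not overlap. A reversal was therefore unlikely from the start, and its absence says little about how firm the directions are. The numbers of genes called moved with the processing. The self-test shows that changes of 1.5-fold were mostly missed except in the mean genotype difference. In the interactions it recovered 44.8%, 47.8% and 47.8% of 2-fold changes, so the absence of interaction genes leaves such changes possible. Its genes were drawn independently, so it does not cover spread that genes share within a library, and real recovery may be lower. For the alternatives below the cause was not tested.

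DESeq2, which also called 9 to 28 unchanged genes per contrast in the self-test against 0 to 10 in edgeR, called 225, 318 and 237 genes for wild-type PBS against uninjected, S. aureus against uninjected and S. aureus against PBS, against 80, 193 and 78. It called 220 and 616 for RNAi-labelled PBS and S. aureus against uninjected, against 66 and 331. For the genotype difference it called 422 as the mean and 115, 74 and 196 in uninjected, PBS and S. aureus flies, against 246, 28, 35 and 42, and for the interactions of S. aureus with uninjected and with PBS 1 and 1, against 0 and 0. A replicate block by Set number gave 121, 296 and 135 genes in the 3 wild-type contrasts, 115 for RNAi-labelled PBS against uninjected, 402 for the mean genotype difference and 107 for the genotype difference after S. aureus. The correlations did not settle whether Set numbers pair the libraries. Of 45 correlations between libraries sharing a Set number 20 were above 0.1, with a median of 0.094 against −0.009 for different numbers. Of 18 libraries 12 were closest to their own Set. These values lean towards some sharing within Sets, which the main fit leaves out. Only the contrasted groups gave 34 and 27 genes for wild-type PBS and S. aureus against uninjected, 151 for RNAi-labelled S. aureus against uninjected and 0, 14 and 13 for the genotype difference in uninjected, PBS and S. aureus flies, the 0 in edgeR beside 550 genes at an unadjusted p under 0.05 and 115 in DESeq2 on all libraries.

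Total counts only gave 48 genes for wild-type PBS against uninjected, 175 and 1966 for RNAi-labelled S. aureus against uninjected and against PBS, and 16 and 23 for the genotype difference in uninjected and PBS flies. Under it the medians of 4 called lists turned in RNAi-labelled PBS against uninjected (Imd, JNK, oxidative stress and RNA-binding), 4 in RNAi-labelled S. aureus against PBS (phagosome, glycolysis, ecdysone and RNA-binding) and 1 in the genotype difference after PBS (oxidative phosphorylation). The scaling moved the median of all genes by −0.16, 0.25 and −0.08 in these contrasts, so small list medians turn with it whatever their members do relative to other genes. Library weights gave 53, 128 and 170 genes in the wild-type contrasts, 229 for RNAi-labelled PBS against uninjected and 10 and 103 for the genotype difference in uninjected and PBS flies. For RNAi-labelled PBS against uninjected no count filter gave 37 and limma-voom 31. Of 168 list calls at the preset correlation, 8 held with an estimated correlation and 30 with fry, and the replicate block gave 175. Leaving out some 1 library moved the median of 113 of the 168 by more than 1.5 times and turned 8. The A2bp1 difference of −0.05 became 0.00 with library weights and 0.01 without wild-type uninjected replicate 3, with a range of −0.11 to 0.01 over the left-out libraries and adjusted p-values of 0.554 to 0.999 over all alternatives.

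With 1 library left out, counts ranged from 9 to 77, 107 to 253 and 5 to 73 in the wild-type contrasts in the order above, and from 6 to 47, 95 to 454 and 155 to 1153 in the RNAi-labelled ones. They ranged from 171 to 417 for the mean genotype difference, 4 to 51, 8 to 45 and 14 to 46 within uninjected, PBS and S. aureus flies, and 0 to 0, 0 to 1 and 0 to 1 for the interactions.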

Other observations

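The gene lists were planned, and the tests of explanations, neighbouring genes and other splits of the libraries were chosen after the results were seen. Cell cycle transcripts in wild-type libraries had medians of −0.21 after PBS (29 of 31 values negative, camera adjusted p = 5.96e-06, adjusted p = 0.73 with an estimated correlation) and −0.20 after S. aureus (camera adjusted p = 3.3e-05, adjusted p = 0.45 with an estimated correlation), while 0 genes passed over all genes or over the list alone. Without wild-type uninjected replicate 3, whose mean of these genes lay highest in its group, these medians were −0.07 and −0.08, and the one after S. aureus was −0.31 without replicate 1. Both comparisons use the same uninjected libraries, so the likeness of the medians is expected in part from those libraries. In RNAi-labelled libraries after S. aureus the median against uninjected was 0.31 with 0 members past the threshold (camera adjusted p = 2.86e-05, adjusted p = 0.662 with an estimated correlation), beside a median of 0.36 with 1 of 13 values negative for germline and nurse cell genes. In the neuron and eye list 3 of 19 members fell in RNAi-labelled S. aureus against PBS libraries, repo (−0.86), futsch (−0.73) and ChAT (−0.72), also 3 when adjusted over the list alone. All 19 values were negative (camera adjusted p = 0.00386, adjusted p = 0.688 with an estimated correlation). The cell types behind these calls were not tested. Of 18 iron and metal genes Mvl rose in wild-type flies after S. aureus (1.20; 2 when adjusted over the list alone; camera adjusted p = 0.00828, adjusted p = 0.386 with an estimated correlation). Of 6 lamellocyte markers cher rose in the same comparison (0.81; 1 when adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.386 with an estimated correlation). Of 31 extracellular matrix and adhesion genes Fas3 was lower in RNAi-labelled libraries (−0.39; 2 when adjusted over the list alone; camera adjusted p = 0.000392, adjusted p = 0.494 with an estimated correlation), and the list median of −0.16 was −0.10 without wild-type uninjected replicate 2.

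Mitochondrial genome transcripts had medians of 0.41 after PBS in RNAi-labelled libraries (27 of 28 positive, camera adjusted p = 1.74e-06, adjusted p = 0.695 with an estimated correlation) and −0.34 for wild-type S. aureus against PBS (27 of 28 negative, camera adjusted p = 8.75e-07, adjusted p = 0.793 with an estimated correlation), with 0 members past the threshold over all genes or over the list alone. The first was 0.22 without RNAi-labelled uninjected replicate 2 and 0.26 without RNAi-labelled PBS replicate 3, and the second −0.15 and −0.57 without wild-type S. aureus replicate 2 or 3. In RNAi-labelled S. aureus against PBS, Hr39 (−0.48), Blimp-1 (−0.70) and Eip93F (−0.53) fell among 17 ecdysone genes and Syp (−0.61), Sxl (−0.36) and ps (−0.43) among 34 RNA-binding regulators, with 5 and 3 when adjusted over the list alone (camera adjusted p = 0.0114 and 0.0116, adjusted p = 0.605 with an estimated correlation for both). Both medians turned positive under scaling by total counts, which moved the median of all genes by 0.25. The ecdysone median of −0.20 was −0.31 without RNAi-labelled S. aureus replicate 3, and the RNA-binding one of −0.15 was −0.09 without replicate 2 of that group. Over the 13 contrasts no autophagy gene passed (lowest camera adjusted p = 0.142), crystal cell markers held 1 fall, CG10469 (lowest 0.29), ER stress genes 3 falls (lowest 0.109) and secreted signals 3 rises and 3 falls.

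After PBS in wild-type flies the 11 eggshell genes had a median of −1.66 (−2.58 to −1.02) and gut markers −0.84 (quartiles −1.25 to −0.34). Less RNA carried over from whole ovaries is argued against as the whole cause by the 13 germline and nurse cell genes, whose median was −0.01 (−0.40 to 0.34), and less RNA from other tissues as a whole by the 18 muscle markers, whose median was 0.10 (quartiles 0.04 to 0.24). A change in late follicle cells, fat body and gut after wounding, with their RNA carried into the preparation, may be an explanation and was not tested.

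A2bp1 was not lower in the RNAi-labelled libraries. Libraries swapped between the genotypes are argued against, since 18 of 18 libraries lay nearer to their own genotype by 50 genes chosen without them. A2bp1 reads from cells outside the driver's expression could hide a fall and stay open: A2bp1 had rho = −0.36 (permutation p = 0.147, adjusted 0.419) and r = −0.33 (permutation p = 0.188, adjusted 0.564) with the plasmatocyte marker mean over 18 libraries, and r was −0.22 without the 2 farthest. With the neuron and eye marker mean it had rho = 0.22 (permutation p = 0.387, adjusted 0.419) and r = 0.16 (permutation p = 0.528, adjusted 0.697) over 18 libraries, and r was 0.51 without the 2 farthest. A hairpin that lowers the protein and not the transcript was not tested.

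Genes called between the genotype labels may reflect strain background in few chromosome segments: 23 pairs of neighbouring genes were both called, against a mean of 6.41 and a highest of 16 in 10000 random sets (one-sided permutation p = 1e-04, the smallest they can give). The wild-type S. aureus response gave 19 such pairs against 3.89 (one-sided permutation p = 1e-04), and 14 of the 23 pairs, Hayan and psh among them, had the same sign, so the test does not tell linkage from gene clusters.

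For the mean genotype difference the real grouping gave 246 genes, and the highest of the other drawn splits gave 3. The real grouping was the only 1 of 100 splits to give as many, the smallest share that 100 splits can give. Splits that mix the genotype labels widen the spread of genes that differ, which lowers their counts. A random grouping of these libraries is thus an unlikely source of the count, and is not excluded. The other contrasts have 10 splits each, 1 of 10 reaching the real count, too few for a share under 0.05. The real and highest other counts were 80 and 16, 193 and 1, and 78 and 0 in the wild-type contrasts of PBS and S. aureus with uninjected and S. aureus with PBS. They were 66 and 0, 331 and 0, and 1017 and 0 in the RNAi-labelled ones, and 28 and 4, 35 and 0, and 42 and 3 for the genotype difference in uninjected, PBS and S. aureus flies.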
